A study of Mus musculus with 8 samples.

How the data were processed

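The samples were in vitro polarized regulatory T cells (Tregs) of wild-type C57BL/6 mice. Per the labels' protocols, CD4+ T cells from spleen and lymph nodes were positively selected and cultured on plates coated with anti-CD3 (5 µg/mL). The medium held anti-CD28 (0.5 µg/mL), IL-2 (100 U/mL), TGF-β (5 ng/mL) and blocking antibodies against IL-4, IL-12 and IFN-γ. After 72 h the cultures were divided, and BMS309403, a small-molecule inhibitor of fatty acid-binding proteins used here against FABP5, was added to part of them at 50 µM. The labels give no duration of exposure and no vehicle. RNA was extracted with a column kit, and stranded poly(A)-selected libraries were sequenced on an Illumina HiSeq.

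Each of the 8 libraries, 4 control and 4 treated, has a file of counts deposited by the authors. Per the submitters' processing notes, the tools were STAR, featureCounts, DESeq2 and deepTools and the genome build was GRCm38. The notes give no versions, roles or annotation release. The deposited counts are whole numbers of reads per Ensembl gene and are not normalized. Whether reads were assigned by strand, and how reads with several matches were treated, is not given in the sources used here. Genes that share reads with a near-identical copy, and overlapping or antisense genes, are therefore uncertain.

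All files list the same 53465 gene IDs. Symbols were found for 53274 of them in the GENCODE M21 annotation of GRCm38, which also gave coordinates, and the other 191 held 0.034% of all counts. Groups and replicate numbers were taken from the titles and descriptions. The labels do not say whether replicates came from separate mice or cultures, so p-values measure the spread between these samples, which may be technical. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom between 3.08 and 24.2 over genes with a summed count of at least 20. No library was therefore counted as a duplicate.

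Genes were tested with edgeR (version 4.0.16, R 4.3.3) by the quasi-likelihood F-test after filterByExpr at its default settings and TMM normalization. The model held the treatment alone, with 6 residual degrees of freedom, and 14443 genes were tested. P-values were adjusted by the Benjamini-Hochberg method and genes under an adjusted p of 0.05 were called. Every adjusted p of a gene in the text comes from this test unless another is named. The SE of a log2 fold change was derived from the F statistic, and intervals of 95% used the t distribution with 6 degrees of freedom. CPM values are counts scaled to the TMM-adjusted library size, given as mean ± SD of 4 libraries. A fold change is the fitted value, so that it can differ slightly from the ratio of mean CPM.

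Before the data were examined, 50 gene lists were fixed, covering T cell lineages and signalling, interferon and nucleic acid sensing, mitochondria, lipid and sugar metabolism, stress, proliferation, other cell types and RNA quality. A single fixed member (1 alias) matched no ID. Lists with at least 5 tested members, 47 in all, were tested with camera (limma 3.58.1) at its preset inter-gene correlation of 0.01, with adjustment over the 47 lists. Camera with a correlation estimated per list and fry, which tests whether a list's genes move on balance in a single direction, were run beside it. For lists of other cell types the summed CPM per library was compared by an exact two-sided permutation test over 70 arrangements, as were 7 measures per library. The smallest p this test can give is 0.0286 with 4 libraries against 4, and also with 3 against 4.

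Genes named in the text follow a rule fixed beforehand. It takes 15 genes chosen for the study's subject, and the 12 largest rises and 12 largest falls among called genes with a mean of at least 5 CPM and no overlap between the groups. Symbols that mark a predicted gene or a pseudogene, and IDs without a symbol, were left out of these; Mx2, annotated as a polymorphic pseudogene, has no such symbol and was kept. It also takes up to 4 called members per list, by size of change, and members that were not called only with their values. Members were taken strictly in order of size, from the largest; how many of the 4 to name in each list was settled after the values were seen. Some genes that this rule would name are not reported here. The genes mt-Co1, mt-Rnr2, Ly6e and Ifi47 fall outside this rule and were chosen after their values were seen, as were the families and sets of the closing section.

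The replicate numbers of the titles recur in both groups. The correlation across genes between the deviations of same-numbered libraries from their group means was 0.384, 0.145, 0.106 and 0.264 for numbers 1 to 4. All 4 exceeded 0.1, so the numbers were taken to pair the samples, although the labels do not say so. Of the 8 libraries, 7 correlated best with their own number, while treated replicate 2 correlated best with control replicate 4 (0.208). A fit with the number as a block was planned as an alternative, and its value is given where it changes a call. The main model left this pairing out, so its p-values do not use it. It called 5311 genes, against 7573 with the block.

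Other alternatives fixed beforehand were size factors of the DESeq2 kind, total counts without TMM, TMM without mitochondrial and ribosomal protein genes, no filter, a filter of at least 1 CPM in 4 libraries, DESeq2 (1.42.0), limma-voom, a minimum fold of 1.5 with glmTreat, and leaving out each library. For the mitochondrial share these were a denominator without ribosomal protein genes and all mitochondrial genes. Added after the data were seen were the block with GC content and length trends removed (loess span 0.5) and the block with estimated list correlations. The steps were tested on simulated counts drawn from the means, depths and dispersions of these libraries, with 200 of 14289 genes changed. For this comparison, 28 of 50 genes changed 1.25-fold, 34 of 50 changed 1.5-fold, 41 of 50 changed 2-fold and 47 of 50 changed 4-fold were recovered, and 7 of 157 calls were false. In these simulated counts, where no list had been shifted as a whole, camera called 1 of 47 lists, fry called 5 and camera with an estimated correlation called 0. Genes were drawn independently there, so these counts cannot show how the list tests behave where members are correlated. The changed genes were picked at random and could belong to lists, so fry's calls need not be false.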

Results

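RNA was sequenced from mouse Tregs polarized in culture and kept without drug (control, n = 4) or with 50 µM BMS309403 (n = 4). BMS309403 is an inhibitor of fatty acid-binding proteins, which carry fatty acids inside cells. Total counts per library lay between 32.9 M and 44.6 M and averaged 37.9 ± 5.51 M in control and 40.4 ± 1.66 M in treated libraries (SD, n = 4). The comparison of the arms asks how 50 µM BMS309403, used here against FABP5, changes gene expression in Tregs. The series title ties this question to mitochondrial integrity. The series holds no other group, and the labels give no vehicle. Effects of blocking FABP5 thus cannot be told apart from other effects of the compound or of a solvent.

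Treatment changed a large part of the transcriptome, mostly by small amounts. Among called genes averaging at least 5 CPM, interferon-stimulated genes gave the largest rises, with Mx1 16.9-fold and Isg15 9.04-fold higher. The largest falls in that range were those of Stra6, a membrane receptor for retinol uptake, which was 33.4-fold lower, and Dhrs3, a retinaldehyde reductase, which was 29.2-fold lower. With the replicate block, 3845 genes were higher and 3728 lower. The main test, edgeR's quasi-likelihood test without that block, called 2694 of 14443 genes higher and 2617 lower at an adjusted p under 0.05. At least 2-fold changes were seen in 355 of the higher and 224 of the lower genes, while 73.8% of the calls were smaller than 1.5-fold. When the test required a change of more than 1.5-fold, 342 higher and 195 lower genes passed. All 4 libraries of one group lay above all 4 of the other for 33.8% of tested genes, against 2.86% by chance. The first principal component, with 60.1% of the variance, parted the groups. On the second, with 14.8%, replicate 1 of each group lay highest.

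**Figure D1:**
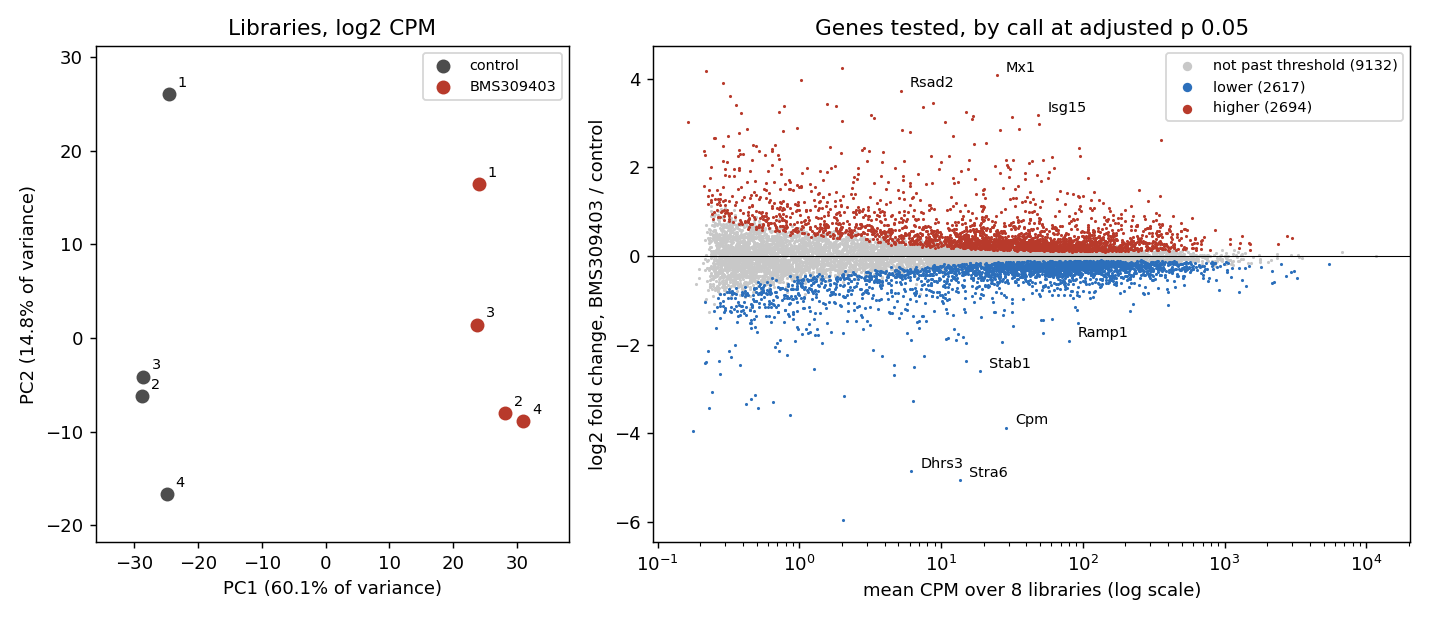
Left, the 8 libraries on the first and second principal components of log2 CPM, with replicate numbers. Right, log2 fold change (BMS309403 over control) of each tested gene against its mean CPM on a log scale, coloured by call; 2694 genes were higher and 2617 lower.

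Of the 12 largest rises under the naming rule, 10 belonged to the fixed list of the type I interferon response: Mx1, Rsad2, Ifi44, Ifit3b, Oas2, Isg15, Ifit3, Mx2, Usp18 and Oasl2. Mx1 (ENSMUSG00000000386, chromosome 16, 97447035 to 97462907 on the minus strand in GRCm38) encodes an antiviral GTPase. It went from 2.80 ± 0.518 to 46.9 ± 5.45 CPM (SD, n = 4), a log2 fold change of 4.08 (SE 0.12, edgeR adjusted p = 1.19e-09). Rsad2, which encodes viperin, rose 13.2-fold and Ifi44 rose 10.9-fold. The other rises were those of Atf3, a stress-induced transcription factor, from 3.43 to 30.4 CPM, and Plaur, the urokinase receptor, from 2.38 to 19.1 CPM.

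Stra6 (ENSMUSG00000032327, chromosome 9, 58063788 to 58153996 on the plus strand) went from 26.6 ± 2.22 to 0.795 ± 0.107 CPM (SD, n = 4), a log2 fold change of -5.06 (SE 0.11, edgeR adjusted p = 1.30e-10). Dhrs3 went from 11.9 to 0.408 CPM and Cpm, which encodes carboxypeptidase M, from 53.9 to 3.67 CPM. The other large falls were those of Tmem273 (9.63-fold), Stab1 (6.10-fold), Fbln2 (5.69-fold), Adssl1 (5.18-fold), Rap1gap2 (12.5 to 2.60 CPM), St8sia6 (3.89-fold), Cttn (3.88-fold), Ramp1 (3.76-fold) and Art2b (3.74-fold). Stab1 encodes a scavenger receptor, Fbln2 an extracellular matrix protein, Cttn the actin-binding cortactin and Ramp1 a co-receptor for the neuropeptide CGRP.

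The type I interferon response rose almost as a whole. Of 51 tested members 49 were higher and 0 lower, also when adjusted over the list alone, with a median log2 fold change of 1.37. The list also holds the 9 genes that the closing section uses as interferon gamma genes. Cxcl10, a chemokine, rose 10.5-fold, though only to 3.31 CPM. The members not past the threshold were Ly6e (log2 fold change 0.11, adjusted p = 0.197) and Ifi47 (0.09, adjusted p = 0.572). With the replicate block both passed (adjusted p = 0.0188 and 0.0312), as did Ly6e without control replicate 1 (0.0384). Camera gave the list an adjusted p = 1.11e-129. It was the only list past the threshold with an estimated correlation (adjusted p = 0.0269), and with the replicate block and an estimated correlation its adjusted p was 0.149.

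In the list of cytosolic nucleic acid sensing, 9 of 15 tested members rose and 1 fell, or 10 and 1 adjusted over the list alone. The DNA-binding Ifi204 rose 15.7-fold to 1.92 CPM and Ifi203 rose 1.91-fold to 452.3 CPM. In control libraries Ifi204 averaged 0.123 CPM, with replicate 1 at 0.279 against at most 0.135 in the others, so its fold is uncertain. Cgas (chromosome 9, 78430526 to 78443237, minus strand), the cytosolic DNA sensor, rose 1.62-fold from 13.2 ± 1.80 to 21.3 ± 1.12 CPM (SD, n = 4; edgeR adjusted p = 7.50e-05). Tmem173, which encodes STING, was 1.17-fold higher (log2 fold change 0.22, SE 0.07, adjusted p = 0.019). Its adjusted p was 0.0608 without control replicate 2, 0.0688 without control replicate 3 and 0.0515 without treated replicate 1. Camera gave the list an adjusted p = 0.00912, but with an estimated correlation its adjusted p = 0.178. Ifnb1, the gene for interferon beta, had 2 counts in the control and 11 in the treated libraries and was too low to test.

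**Figure D2:**
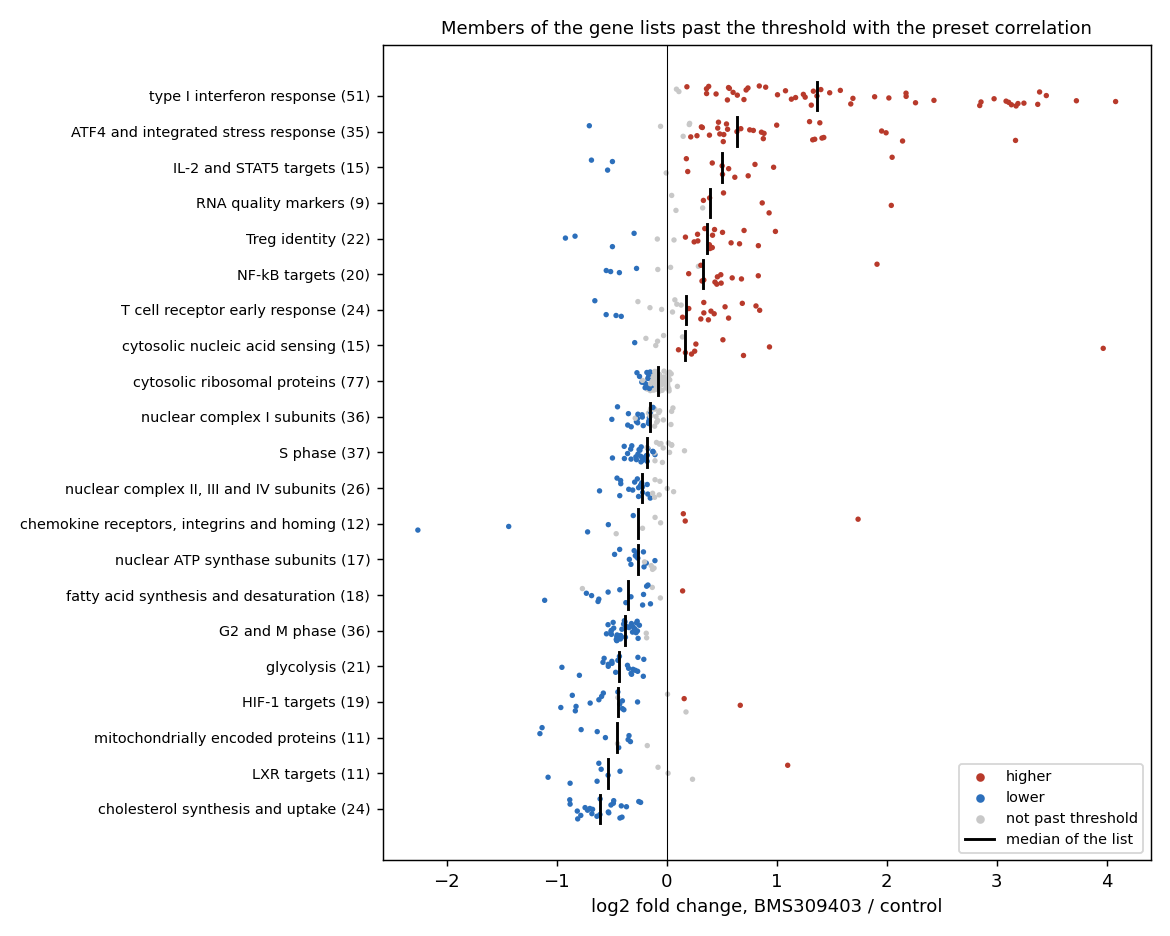
Log2 fold change (BMS309403 over control) of every tested member of the 21 gene lists past the threshold with camera's preset correlation, with the number of tested members in parentheses. Each point is a gene, coloured by its call, and the bar is the list median, which runs from -0.61 for cholesterol synthesis and uptake to 1.37 for the type I interferon response.

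Sterol and fatty acid synthesis genes fell together. All 24 tested genes of cholesterol synthesis and uptake were lower, also when adjusted over the list alone, with a median log2 fold change of -0.61. Acat2 and Dhcr7, the latter acting at the last step to cholesterol, were both 1.84-fold lower, and Lss, the lanosterol synthase, 1.76-fold lower. Hmgcs1 (ENSMUSG00000093930), which makes HMG-CoA early in the pathway, went from 507 ± 15.9 to 289 ± 9.90 CPM (SD, n = 4; edgeR adjusted p = 6.15e-08). Of 18 genes of fatty acid synthesis and desaturation, 14 fell and 1 rose (15 and 1 adjusted over the list alone). Scd1, a stearoyl-CoA desaturase, was 2.16-fold lower and Fads2 1.66-fold lower. Camera's adjusted p was 2.73e-33 for the cholesterol list and 5.47e-11 for fatty acid synthesis; both had an adjusted p = 0.0558 with an estimated correlation.

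Among targets of the oxysterol receptor LXR, 7 of 11 fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 9.56e-07, and adjusted p = 0.0558 with an estimated correlation). The member with the largest change was the single rise, Abcg4, 2.14-fold higher at 0.599 CPM (adjusted p = 0.0247). It lost its call without control replicate 2 (adjusted p = 0.0825), treated replicate 2 (0.0536) or treated replicate 4 (0.0755). Mylip, which promotes degradation of the LDL receptor, was 2.11-fold lower. Abca1 and Abcg1, which export cholesterol, were 1.84-fold and 1.55-fold lower. This list shares Srebf1 and Scd2 with fatty acid synthesis.

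Fabp5 (ENSMUSG00000027533, chromosome 3, 10012548 to 10016607, plus strand), the gene of the drug's target in this study, was at 178 ± 23.7 CPM in control and 153 ± 18.3 CPM in treated libraries (SD, n = 4). Its log2 fold change was -0.22 (95% interval -0.47 to 0.02), with an edgeR adjusted p = 0.0934. It passed the threshold with the replicate block (adjusted p = 1.29e-05), without a filter on low counts (0.0229), without control replicate 4 (0.0288) and without treated replicate 1 (0.0368). Fabp4 and Fabp3 each had 0 counts in the control and 1 in the treated libraries. In the list of FABP genes, fatty acid uptake and activation, 2 of 14 tested members rose and 3 fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.227). Cd36, a fatty acid transporter, rose 5.22-fold to 4.63 CPM, Scarb1, the HDL receptor, was 1.48-fold lower and Acsl1 rose 1.45-fold.

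Among PPAR targets and lipid droplet genes, 4 of 17 rose and 5 fell, or 4 and 6 adjusted over the list alone (camera adjusted p = 0.815); the median (0.02) and mean (0.03) log2 fold changes lay above 0 while camera's direction was down. After Cd36, the largest changes were those of Pparg, 2.89-fold lower at 0.594 CPM, and Dgat2, which makes triglyceride, 2.36-fold higher. In beta-oxidation, 2 of 23 rose and 6 fell, or 2 and 7 adjusted over the list alone (camera adjusted p = 0.302). Acot2 rose 2.01-fold and Acaa2 was 1.34-fold lower. Cpt1a, the gate of fatty acid entry into mitochondria, had a log2 fold change of 0.02 (95% interval -0.15 to 0.18, adjusted p = 0.878).

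Many messenger RNAs of the respiratory chain were lower, both among those encoded in mitochondria and among those of the nucleus, though the 4 lists did not pass with an estimated correlation. Of 11 tested mitochondrially encoded protein genes, 9 fell and 0 rose (10 and 0 adjusted over the list alone), with a median log2 fold change of -0.45. mt-Co2, mt-Atp6 and mt-Co3 were 2.22-fold, 2.19-fold and 1.55-fold lower but lay at 0.718, 0.541 and 1.01 CPM in control, far under mt-Co1, so their changes are uncertain. mt-Co3 lost its call without control replicate 1 (adjusted p = 0.0902), control replicate 2 (0.0590), treated replicate 1 (0.0525), treated replicate 2 (0.106) or treated replicate 4 (0.0839). mt-Cytb, a complex III subunit, was 1.72-fold lower, from 1150 ± 57.4 to 670.2 ± 98.6 CPM (SD, n = 4). mt-Co1, named after its values were seen, went from 3448 to 2717 CPM (log2 fold change -0.34, SE 0.08, adjusted p = 0.00734).

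The 13 mitochondrially encoded protein genes took 0.673% ± 0.0574 of all counts in control and 0.513% ± 0.0533 in treated libraries (SD, n = 4). An exact permutation test gave p = 0.0286, the smallest it allows, and 0.1 after adjustment over 7 measures per library. Without treated replicate 3 the exact p was 0.0571, and with the replicate block a sign-flip permutation test over the 4 pairs gave 0.125, the smallest it allows. With all mitochondrial genes, the ribosomal RNAs included, the share went from 0.706% to 0.563% (exact permutation p = 0.0286). The ribosomal RNAs themselves moved the other way: mt-Rnr1 rose 1.82-fold, and mt-Rnr2, named after its values were seen, had a log2 fold change of 0.33 (SE 0.05, adjusted p = 0.000195).

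**Figure D3:**
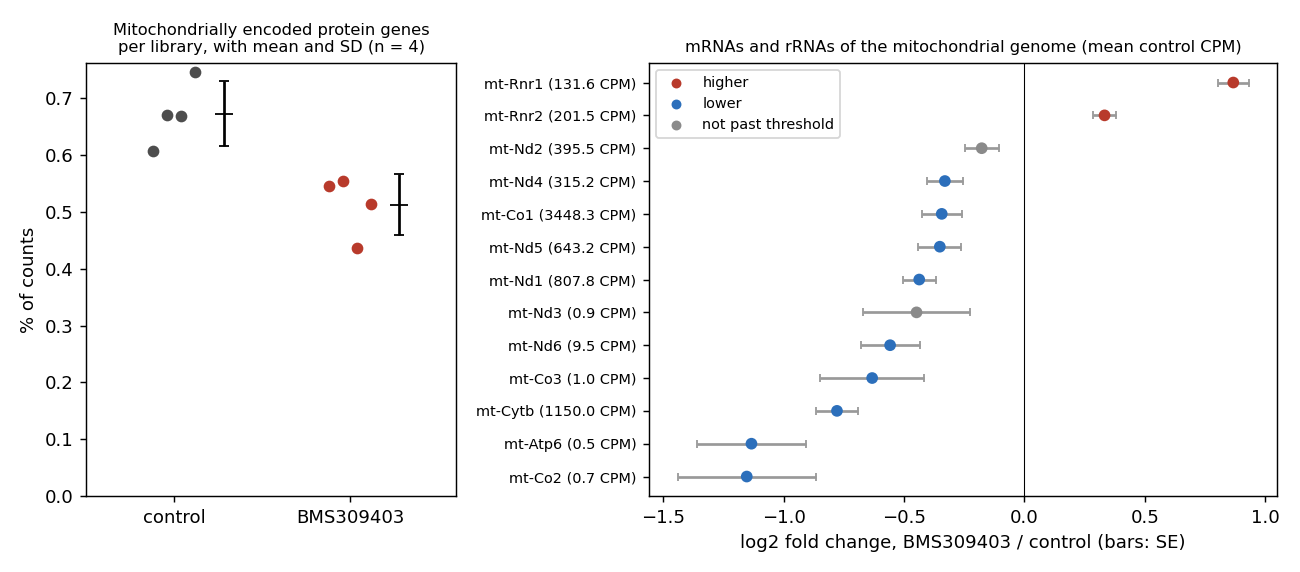
Left, percent of counts from the 13 mitochondrially encoded protein genes in each library, with group mean and SD (n = 4); the treated libraries lie between 0.437% and 0.555% and the control libraries between 0.606% and 0.747%. Right, log2 fold change with SE of the tested mRNAs and rRNAs of the mitochondrial genome, with mean control CPM; 9 mRNAs were called lower and both rRNAs higher.

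Of the nuclear subunits, 17 of 36 of complex I, 19 of 26 of complexes II, III and IV and 13 of 17 of ATP synthase fell, and 0 rose in each list. Adjusted over the list alone, 17, 19 and 16 fell. Ndufb2 and Ndufv3 of complex I were 1.41-fold and 1.36-fold lower, Uqcrh and Ndufa4 1.53-fold and 1.37-fold lower, and Atp5k and Usmg5 of ATP synthase 1.39-fold and 1.35-fold lower. Camera gave adjusted p-values of 0.00107 for the mitochondrially encoded genes, 0.00144 for complex I, 0.000115 for complexes II to IV and 0.00136 for ATP synthase. With an estimated correlation these were adjusted p = 0.291, 0.76, 0.678 and 0.678.

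The lists of mitochondrial structure and of mitochondrial DNA upkeep passed with neither camera nor fry. For cristae, fusion, fission and cardiolipin, 2 of 29 rose and 8 fell in either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 0.392). Chchd6 and Mief1 were both 1.33-fold lower, Chchd6 not without control replicate 2 (adjusted p = 0.0628) or control replicate 3 (0.0645). Opa1, which shapes cristae, had a log2 fold change of -0.01 (95% interval -0.12 to 0.09). For mitochondrial DNA maintenance and biogenesis, 4 of 17 rose and 1 fell in either adjustment (camera adjusted p = 0.735), with Pprc1 1.26-fold and Top1mt 1.21-fold higher. Top1mt lost its call without control replicate 2 (adjusted p = 0.113), 3 (0.113) or 4 (0.0843), or treated replicate 1 (0.108), 2 (0.0847) or 3 (0.0613). Tfam, which packages mitochondrial DNA, had a log2 fold change of -0.01 (95% interval -0.12 to 0.11).

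In mitophagy, 2 of 12 rose and 6 fell, also when adjusted over the list alone; the hypoxia-inducible Bnip3 and Bnip3l were 1.78-fold and 1.51-fold lower. Camera gave that list an adjusted p = 0.191, and 0.0299 with the replicate block, but adjusted p = 0.535 with an estimated correlation. In the TCA cycle, 2 of 20 rose and 4 fell, also when adjusted over the list alone (camera adjusted p = 0.636), with Fh1 1.24-fold lower. Of the mitochondrial ribosomal proteins, 14 of 74 fell and 2 rose, or 12 and 2 adjusted over the list alone, with Mrpl34 1.40-fold and Mrpl41 1.32-fold lower. That list's adjusted p was 0.117, and it passed without treated replicate 1 (0.0332), without control replicate 4 (0.00908), without a filter on low counts (0.0330) and with limma-voom (0.0367), but had an adjusted p = 0.863 with an estimated correlation.

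Glycolytic genes were lower without exception: 21 of 21 fell, also when adjusted over the list alone, with a median log2 fold change of -0.43. Aldoc was 1.94-fold lower, the glucose transporter gene Slc2a3 1.73-fold lower, and Eno1, which encodes an enolase, went from 2667 ± 151 to 1783 ± 221 CPM (SD, n = 4). Camera gave an adjusted p = 3.50e-08, and adjusted p = 0.395 with an estimated correlation. Of HIF-1 targets 14 of 19 were lower and 2 higher (14 and 3 adjusted over the list alone), with Ankrd37 1.95-fold and Selenbp1 1.81-fold lower. Camera's adjusted p was 4.50e-05, and adjusted p = 0.432 with an estimated correlation.

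Targets of ATF4, the transcription factor of the integrated stress response, were higher in 30 of 35 cases and lower in 1 (31 and 1 adjusted over the list alone), with a median log2 fold change of 0.64. Atf3 rose 9.01-fold. Atf5 rose 4.42-fold from 16.2 ± 0.423 to 71.6 ± 11.6 CPM (SD, n = 4), and the amino acid transporter genes Slc7a11 and Slc7a3 rose 3.98-fold and 3.87-fold. Camera's adjusted p was 1.97e-37, and adjusted p = 0.0558 with an estimated correlation.

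Other stress lists were not shifted by camera. In the unfolded protein response of the endoplasmic reticulum, 6 of 21 rose and 2 fell, with Derl3 1.76-fold and Sel1l 1.43-fold higher (adjusted p = 0.218). In the heat shock list 4 of 13 rose and 0 fell, with Hsph1 1.29-fold and Hspa8 1.21-fold higher (adjusted p = 0.722). Among metal and xenobiotic response genes 5 of 9 rose and 2 fell, with Cyp1a1 3.75-fold higher at 2.49 CPM and Ahrr 2.12-fold higher at 1.88 CPM (adjusted p = 0.55). Among p53 targets 5 of 20 rose and 3 fell, with Fas higher (log2 fold change 0.68) and Sesn1 1.59-fold lower (adjusted p = 0.779). In the BCL-2 family 3 of 14 rose and 3 fell, with the survival gene Bcl2l1 2.30-fold higher and Bcl2a1b 1.35-fold lower (adjusted p = 0.623, median below 0 but mean and camera's direction up). Bcl2a1b lost its call without control replicate 2 (adjusted p = 0.0547) or 3 (0.0741), or treated replicate 2 (0.0780) or 4 (0.0691). These 5 lists had the same counts adjusted over the list alone.

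Among NRF2 targets 7 of 23 rose and 8 fell, or 8 and 10 adjusted over the list alone (camera adjusted p = 0.767), the median being 0.05 while the mean (-0.08) and camera's direction were down. Osgin1 was 9.01-fold lower, at 0.414 CPM in treated libraries, while Slc7a11 was higher. In the lysosome and autophagy list 4 of 25 rose and 6 fell, or 5 and 6 adjusted over the list alone (camera adjusted p = 0.17). Wipi1 was 1.43-fold lower, but not past the threshold without control replicate 2 (adjusted p = 0.0560).

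Most Treg identity genes were higher. Of 22 tested, 16 rose and 4 fell, also when adjusted over the list alone (camera adjusted p = 0.00104, and adjusted p = 0.07 with an estimated correlation). Cd83 rose 1.98-fold and Ikzf2 (Helios) 1.78-fold, while Nrp1 and Izumo1r (folate receptor 4), both surface markers of Tregs, were 1.89-fold and 1.78-fold lower. Foxp3, the lineage factor of Tregs, went from 950.0 ± 55.6 to 1247 ± 15.3 CPM (SD, n = 4; log2 fold change 0.39, SE 0.05, edgeR adjusted p = 6.05e-05). Il2ra, the high-affinity IL-2 receptor chain, rose 1.33-fold.

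Among effector and suppressive molecules 7 of 20 rose and 5 fell, also when adjusted over the list alone (camera adjusted p = 0.47), the median (0.02) and mean (0.09) lying above 0 while camera's direction was down. Havcr2 (TIM-3) rose 2.38-fold to 2.50 CPM and Areg (amphiregulin) 2.32-fold to 1.36 CPM, while the checkpoint receptor genes Pdcd1 and Tigit were 1.85-fold and 1.82-fold lower. Ctla4 had a log2 fold change of 0.06 (95% interval -0.11 to 0.23, adjusted p = 0.521). Il10 was 1.76-fold higher (log2 fold change 0.82, SE 0.26, adjusted p = 0.0292), at 0.798 CPM in control and 1.38 CPM in treated libraries. It lost its call without control replicate 2 (adjusted p = 0.0947), 3 (0.0762) or 4 (0.0726), or treated replicate 1 (0.0653) or 3 (0.0818). Tgfb1 had a log2 fold change of -0.14 (95% interval -0.29 to 0.02, adjusted p = 0.115). It was called lower with the replicate block (adjusted p = 0.00332), without control replicate 4 (0.0426) and without treated replicate 3 (0.0419).

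**Figure D4:**
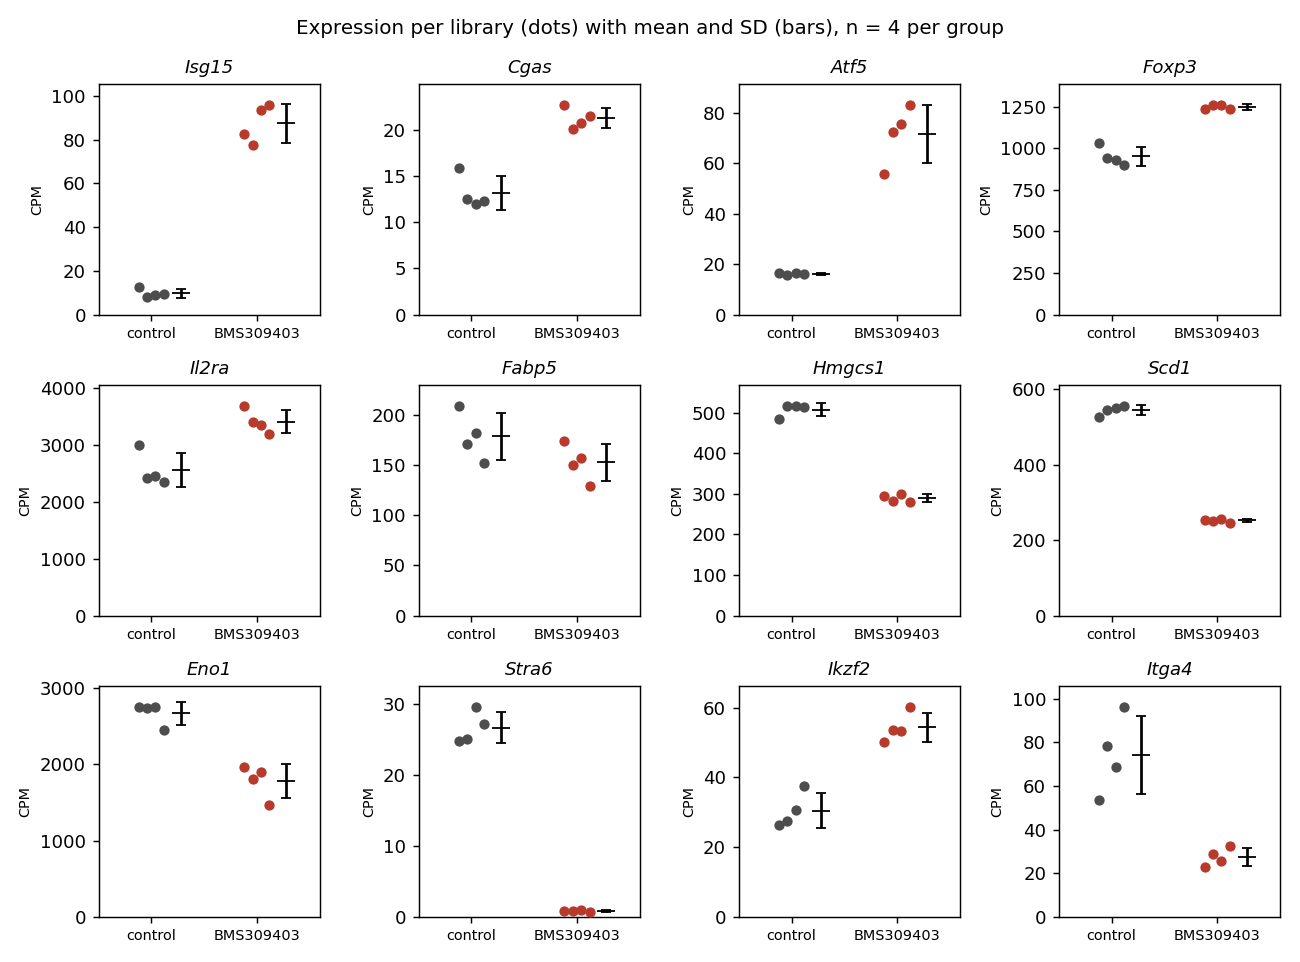
CPM of 12 named genes in each library (dots), with group mean and SD (n = 4, bars); axes start at 0. Fabp5 overlaps between the groups (mean 178 and 153 CPM), while Isg15 (9.74 and 87.4 CPM) and Stra6 (26.6 and 0.795 CPM) do not.

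Several signalling lists were shifted up. Among IL-2 and STAT5 targets 11 of 15 rose and 3 fell, led by Gadd45b (4.14-fold) and the kinase gene Pim2 (1.96-fold); camera's adjusted p was 5.12e-05, and adjusted p = 0.395 with an estimated correlation. Among NF-kB targets 13 of 20 rose and 4 fell, with the cytokine gene Csf2 3.76-fold higher at 2.20 CPM, Icam1 1.78-fold higher and Nfkb2 going from 318 to 509 CPM. Camera's adjusted p was 4.50e-05, and adjusted p = 0.0558 with an estimated correlation. Both lists had the same counts adjusted over the list alone. In the early T cell receptor response 13 of 24 rose and 4 fell, or 13 and 6 adjusted over the list alone, with Dusp1 1.80-fold and Cd69 1.75-fold higher. Camera's adjusted p was 0.00396, and adjusted p = 0.334 with an estimated correlation. Of TGF-β response genes 2 of 17 rose and 8 fell, or 4 and 8 adjusted over the list alone, with Smad6 2.10-fold lower. That list had an adjusted p = 0.0863, and 0.0316 without a filter on low counts, but adjusted p = 0.395 with an estimated correlation.

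Genes of other helper lineages moved in both directions. In the Th1 list 8 of 14 rose and 2 fell. The chemokine receptor gene Cxcr3 was 2.56-fold lower, Ifng 2.42-fold higher and the IL-12 receptor gene Il12rb2 2.32-fold higher. Ifng lost its call without control replicate 2 (adjusted p = 0.0511) or control replicate 3 (0.0516). Camera gave the list an adjusted p = 0.227, and 0.0310 with the replicate block, but adjusted p = 0.678 with an estimated correlation. In the Th2 list 5 of 10 rose and 2 fell (camera adjusted p = 0.191), with the cytokine genes Il9, Il24 and Il13 going from 0.202, 0.212 and 0.470 CPM to 3.82, 1.14 and 1.81 CPM. Replicate 1 held the most Il24, at 0.527 against at most 0.179 CPM in control and 2.01 against at most 1.02 CPM in treated libraries. In the Th17 list 3 of 9 rose and 2 fell (adjusted p = 0.643). Ccl20 was 2.44-fold higher and Il1r1 2.39-fold higher at 0.420 CPM. In the naive and central memory list 3 of 13 rose and 4 fell (adjusted p = 0.425), with Dapl1 1.74-fold lower at 0.943 CPM and Il7r 1.59-fold higher. These 4 lists had the same counts adjusted over the list alone.

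In the homing list 3 of 12 rose and 5 fell, or 3 and 7 adjusted over the list alone. Cxcr5 went from 6.29 to 1.31 CPM, and the integrin gene Itga4 was 2.71-fold lower, while Itgb8, whose product activates TGF-β, rose 3.34-fold to 3.91 CPM. The homing list was shifted down (camera adjusted p = 0.0162), with an adjusted p = 0.138 with an estimated correlation.

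Cell cycle genes were lower by small amounts. In G2 and M phase 34 of 36 fell and 0 rose (36 and 0 adjusted over the list alone), with a median log2 fold change of -0.38; Cenpa was 1.46-fold and Cdca3 1.45-fold lower. In S phase 24 of 37 fell and 0 rose (26 and 0 adjusted over the list alone), with Rrm2 1.41-fold and Ccne1 1.31-fold lower. Camera's adjusted p-values were 7.18e-22 and 0.000245, and adjusted p = 0.0891 and 0.678 with an estimated correlation.

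Among cytosolic ribosomal proteins 13 of 77 fell and 0 rose, but 1 and 0 adjusted over the list alone; Rps25 was 1.21-fold lower. Camera's adjusted p was 0.0286, and adjusted p = 0.857 with an estimated correlation. It was 0.0990 without control replicate 1, 0.0522 without control replicate 2, 0.0680 without control replicate 3, and 0.112 without treated replicate 2 or 4. In ribosome biogenesis and MYC targets 9 of 30 rose and 2 fell, also when adjusted over the list alone, with the lactate dehydrogenase gene Ldha 1.36-fold lower and Ppan 1.31-fold higher. Ppan lost its call without control replicate 2 (adjusted p = 0.0586), 3 (0.0706) or 4 (0.0501), or treated replicate 1 (0.0520). The list's adjusted p was 0.227, and it passed without control replicate 1 (0.00152), with the replicate block (0.0360) and with limma-voom (0.0367), but had an adjusted p = 0.863 with an estimated correlation.

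Markers of other cells that a CD4 selection could carry over were compared as summed CPM. Plasma cell markers went from 392 ± 37.9 to 297 ± 9.39 CPM, macrophage and dendritic cell markers from 152 ± 5.90 to 188 ± 18.5 CPM, neutrophil and mast cell markers from 12.2 ± 0.674 to 15.5 ± 1.47 CPM, and stromal and endothelial markers from 120 ± 4.27 to 104 ± 3.52 CPM (SD, n = 4). Each of these had an exact permutation p = 0.0286 and an adjusted p of 0.05. Each sum was carried by its most abundant gene. Without that gene, a check chosen after the sums were seen, they went from 13.6 to 13.1, 51.7 to 32.9, 0.127 to 0.169 and 2.79 to 4.92 CPM (exact permutation p = 0.629, 0.0286, 0.543 and 0.0286). The macrophage and dendritic cell sum thus fell without Cd74, and the stromal and endothelial sum rose. Most of the former sum in control libraries was H2-Ab1, at 37.9 CPM, which was 1.89-fold lower with treatment. The fall of this sum thus largely follows 1 gene and does not show a general loss of these markers. B cell markers summed to 13.7 and 12.5 CPM, CD8 T and NK cell markers to 109 and 103 CPM, and erythroid and platelet markers to 2.33 and 2.79 CPM, with exact permutation p-values of 0.4, 0.286 and 0.2. Without the most abundant gene of each these went from 10.3 to 9.14, 32.9 to 37.9 and 0.469 to 0.264 CPM (exact permutation p = 0.429, 0.114 and 0.0571), so the direction turned for the last 2. Camera called none of the 4 such lists it could test, with adjusted p-values of 0.722 for B cells, 0.449 for plasma cells, 0.735 for macrophages and dendritic cells, and 0.623 for CD8 T and NK cells.

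In these lists 0 of 11, 1 of 5, 1 of 10 and 3 of 8 members rose and 1, 2, 2 and 1 fell, with the same counts adjusted over the list alone. Cd79b was 1.40-fold lower, from 2.10 CPM in control libraries. Ighm, which made up 379 and 283 CPM of the plasma cell sum, was 1.34-fold lower, Sdc1 2.75-fold lower at 1.16 CPM and Derl3 higher, as above. Adgre1 went from 0.565 to 0.137 CPM, and H2-Ab1 was 1.89-fold lower, while Cd74 rose from 99.9 to 156 CPM. Eomes was 1.99-fold higher at 3.48 CPM, Klrk1 1.62-fold higher at 0.993 CPM and Klrc1 higher, from 5.93 to 9.46 CPM; Klrk1 lost its call without control replicate 3 (adjusted p = 0.0508).

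RNA quality markers moved with treatment, beside every gene group described above. Of 9 tested, 6 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.00228, and adjusted p = 0.0776 with an estimated correlation). They included the small nuclear RNA Rn7sk, 4.12-fold higher at 2.87 CPM, mt-Rnr1 as above, and the nuclear RNA Malat1, 1.91-fold higher from 112 ± 31.8 to 214 ± 93.9 CPM (SD, n = 4). Malat1 lost its call without control replicate 2 (adjusted p = 0.0585), control replicate 3 (0.0539), treated replicate 2 (0.0780) or treated replicate 4 (0.0715). Of 60 small RNAs without poly(A) tails, a set chosen after the data were seen, 10 rose and 0 fell. Among all tested genes 18.7% were higher and 18.1% lower.

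Camera with its preset correlation called 8 lists higher and 13 lower of 47, and with an estimated correlation 1 higher and 0 lower. In simulated counts of independent genes, with no list shifted as a whole, fry had called 5 of 47 lists. Here it called 12 higher and 17 lower, without the cytosolic ribosomal proteins (fry adjusted p = 0.22). It added Th1 (0.0110), Th2 and Th17 (0.0114 each), the BCL-2 family (0.000215), TGF-β response (0.00164), mitophagy (0.00588), FABP genes and fatty acid uptake (0.0247), lysosome and autophagy (0.0186) and plasma cell markers (0.0179), the first 4 up and the others down. Of the 35 ways to split the 8 libraries into 4 and 4, 7, the real one included, gave at least 21 called lists; the other 6 had 3 controls on one side.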

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

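The measurement of each group's most distant library was planned, while which genes it covered followed from the genes named in the text. In 22 of 316 groups of 4 libraries, 1 library lay far from the other 3 by Dixon's test, which divides the gap to the nearest library by the group's range (the ratio given with each value). Chance gives about 1 in 20 groups, or 16, so the number alone is unremarkable; genes are not independent of each other either. Control replicate 1 was the distant library in 12 of the 22.

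In control replicate 1, Il2ra was at 3007 CPM against at most 2465 in the others (ratio 0.831), Cgas at 15.8 against at most 12.5 (0.849), Tmem173 at 298 against at most 253 (0.843) and Ifit3 at 8.86 against at most 5.89 (0.915). Havcr2 was at 2.17 against at most 0.748 CPM (0.938), Ifng at 8.09 against at most 3.03 (0.964), mt-Co3 at 1.43 against at most 0.921 (0.873), Pprc1 at 112 against at most 88.3 (0.876), Top1mt at 7.28 against at most 6.19 (0.859) and Hsph1 at 121 against at most 92.7 (0.926). Hmgcs1 was lower there, at 483 against at least 514 CPM (0.931), and so was Sel1l, at 87.8 against at least 91.5 (0.857). Ifng was also far higher in treated replicate 1, at 16.5 against at most 8.04 CPM (0.930), as was Pim2, at 120 against at most 116 (0.893).

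Control replicate 4 had a lower share of cytosolic ribosomal protein counts, 7.01% against at least 7.51% (0.872). There Ndufv3 was at 79.7 against at least 91.6 CPM (0.859), Eno1 at 2441 against at least 2730 (0.940) and Mylip at 9.16 against at most 7.51 (0.830). In control replicate 3 mt-Rnr2 was at 190 against at least 205 CPM (0.913). In treated replicate 4 Cd69 was at 116 against at most 108 CPM (0.885) and Scarb1 at 54.4 against at least 59.7 (0.956), and in treated replicate 3 Fads2 was at 62.6 against at most 56.8 (0.859).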

How the results depend on the processing

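The correction for GC content and length and the block with estimated list correlations were chosen after the data were seen; the other alternatives were planned. Counts of called genes stayed within 1.5 times of 2694 higher and 2617 lower under the alternatives run, except with a minimum fold of 1.5, which by construction asks for more (342 higher, 195 lower). Leaving out each library gave 2078 to 2939 higher and 2007 to 2779 lower genes. No called gene changed direction, except 1 with the replicate block and the GC and length correction. Total counts without TMM gave 2946 higher and 2365 lower. The replicate block gave 3845 higher and 3728 lower genes. Lists were the least stable result: 8 were called higher and 13 lower, against 1 and 0 with a correlation estimated per list, and 0 and 0 with the replicate block and estimated correlations. The estimated correlation was 0.583 for glycolysis, against the preset 0.01. For NF-kB targets it was -0.00667, below the preset, and that list lost its call too. The cause was not tested. Fry called 12 lists higher and 17 lower. Leaving out each library gave 8 to 9 lists higher and 12 to 14 lower. The share of counts from mitochondrially encoded protein genes differed by -0.160 percentage points. With the replicate block that difference had a p of 0.125, which 4 pairs cannot go below, so this test says nothing of stability. Leaving out each library gave differences between -0.182 and -0.135; without treated replicate 3 (-0.135) the exact p was 0.0571, and the cause was not tested. Beside the genes and lists whose blocked values the report gives, the replicate block changed no other call of a named gene or list. The minimum fold was applied to the counts of genes only. Over the alternatives run for single genes and lists, 80 gene values, all with a library left out, and 48 list values lost their call, 15 and 22 gained it, and the other 3465 and 823 kept direction and side of the threshold. The depth limits what can be said of genes near 1 CPM, such as Il10, and of Ifnb1, Fabp3 and Fabp4, which were too low to test.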

Other observations

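The gene families, the retinoid list, the interferon gene sets, the small RNA set and all tests of explanations were chosen only after the result was seen, except the test of histone mRNAs and the counts over other splits; a few histone genes had been seen before. The example of each family is its largest change among members averaging at least 5 CPM. Of 20 families, Schlafen genes rose in 7 of 7 tested cases, with Slfn8 going from 16.8 to 61.3 CPM (camera adjusted p = 4.17e-23; adjusted p = 0.0164 with an estimated correlation). Of the IFI200 family 10 of 11 rose, with Ifi213 going from 6.05 to 35.5 CPM while Aim2 did not pass (adjusted p = 9.98e-27; 0.0238 with an estimated correlation), and 11 of 11 guanylate-binding protein genes rose, with Gbp10 going from 3.99 to 18.9 CPM (adjusted p = 9.80e-21; 0.0344 with an estimated correlation). MHC class II genes were lower in 8 of 9 cases and higher in 0, with H2-DMb2 going from 10.2 to 3.68 CPM (adjusted p = 2.32e-09; 0.0344 with an estimated correlation). The summed macrophage and dendritic cell markers without Cd74 fell from 51.7 to 32.9 CPM (exact permutation p = 0.0286). That sum is not separate from the MHC class II genes, since most of it in control was H2-Ab1 (37.9 CPM, 1.89-fold lower with treatment). Adgre1 went from 0.565 to 0.137 CPM. A sum of 8 macrophage and dendritic cell genes, near the floor, overlapped between groups. It lay at 0.991 to 1.31 CPM in control and 0.765 to 1.66 CPM in treated libraries. Of 8 SLC7 amino acid transporter genes 6 rose, with Slc7a3 going from 6.40 to 24.8 CPM (adjusted p = 3.81e-07; 0.0344 with an estimated correlation).

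Of 12 tested interleukin genes 10 rose and 0 fell, most of them near 1 CPM, with Il16 going from 192 to 214 CPM (adjusted p = 6.99e-05; adjusted p = 0.115 with an estimated correlation). Of 14 tubulin genes 10 fell and 0 rose, with Tubb6 going from 76.9 to 28.1 CPM (adjusted p = 5.67e-05; adjusted p = 0.17 with an estimated correlation). Transcripts of 18 type I interferon genes summed to 6 counts in control and 59 in treated libraries, 0 to 4 and 12 to 18 per library, with an exact permutation p of 0.0286, the smallest it allows.

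For the rise of interferon-stimulated genes, scaling is argued against by the list median, which was at least 1.36 under each scaling alternative. A response to interferon gamma cannot be told apart from one to type I interferon: 12 genes that mainly follow type I interferon had a median 2.56 above that of 9 gamma genes (3.12 and 0.56), and still far above it with Cxcl9 and all guanylate-binding proteins added (0.87). The 12 and the 9 genes all belong to the fixed list of the type I interferon response. The sets were chosen after the values were seen, so the comparison excludes nothing. Their values overlapped in Cxcl9 alone, which lay under 1 CPM, and the medium held an antibody against IFN-γ. Antigen-presenting cells left after the CD4 selection stay open as a source of interferon, as does a response of the Tregs to treatment: 6 marker genes, near the floor, were not raised (at most 0.636 CPM in a treated library, 0.465 to 0.876 in control), but a few cells could be enough.

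Mitochondrial mRNAs fell while the mitochondrial rRNAs rose. Reads shared with nuclear copies are argued against by the 6 mRNAs over 200 CPM, with a median of -0.35 and 5 called lower. Less mitochondrial RNA in total cannot be told apart from a change in the mRNAs alone: the lower of the rRNA log2 fold changes was 0.33, but weaker poly(A) selection in the treated libraries could raise the rRNAs and stays open. Histone mRNAs without poly(A) tails, 35 genes outside the fixed lists, had a median of -0.43, with 1 higher and 11 lower. Histone genes of the RNA quality list were left out. Of those tested, Hist1h1c and Hist1h2bc rose (log2 fold change 0.39 and 0.52), while Hist1h4i did not pass (0.04). The median met the bound set beforehand against weaker poly(A) selection. That bound was judged wrong after the result was seen, because histone mRNAs follow S phase, whose genes also fell (median -0.18). The 60 small RNAs without tails, added for that reason, had a median of 0.25, with 10 higher and 0 lower. Among all tested genes 18.7% were higher and 18.1% lower, and these RNAs averaged 4.28 CPM or less. Their share of rises was not above that of all genes, but 0 of them fell, against 18.1% of all genes. This one-sided direction is the one that weaker poly(A) selection would give. At such low CPM these RNAs do not decide the question. A drug effect on mitochondrial transcripts stays open beside weaker poly(A) selection.

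Stra6, Dhrs3, Nrip1 and Itga4, which are linked to retinoic acid, fell, and lower retinoic acid receptor signalling is a candidate explanation. The other 17 tested genes of a retinoid list had a median log2 fold change of -0.32, with 9 lower and 4 higher. That lay at percentile 0.01 of 10000 random lists matched on expression, the smallest these can give. The list was written after fold changes had been seen, and random lists ignore that related genes can move together. The percentile is therefore no independent support. Of its members, 5 were also in lists fixed earlier. Scaling and a GC or length trend are argued against, since the smallest fall of the first 4 genes was -1.42 under the scaling alternatives and -1.51 after the trend was removed. A loss of macrophages or dendritic cells is argued against by 8 of their genes, which summed to 1.13 CPM in control libraries against 26.6 CPM for Stra6. Whether the medium held retinoids was not tested.

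Of the 35 splits of the 8 libraries into 4 and 4, only the real one, 1 of 35, gave as many called genes (5311, against at most 1 in the others). That share is under 0.05 if the libraries are taken as unpaired. The other splits mixed treated and control libraries on each side, which widens the spread within sides, so few calls were likely there. The numbers were taken to pair the samples, and only 8 splits part all pairs, too few for a share under 0.05. With pairing, this test therefore cannot decide on chance for the count of genes, whatever the data. For lists, 7 of 35 splits gave at least the 21 of the real split, with up to 23, so this count does not exclude chance for the lists, although the other 6 all had 3 controls on one side and kept part of the treatment difference. The 16 other splits with 3 controls on one side gave 14 to 23 lists and the 18 with 2 on each side 0 to 15. Evenly mixed splits mostly gave fewer lists, but the real split did not give the most. Among the other 7 splits that part all same-numbered pairs, edgeR called 0 genes and the most lists was 21; with the real one these make 8 splits, too few for a share under 0.05.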
